A study of Danio rerio with 17 samples.

How the data were processed

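Cells were picked by hand from the epidermis of adult zebrafish with fluorescent reporters and lysed for SMART-seq2 complementary DNA amplification, and libraries were sequenced as paired reads. The series text says that replicates come from independent experiments. Each of the 17 libraries is 1 sample, grouped by its label into MLCs (4), cLCs (4), keratinocytes (3), neutrophils (3) and T cells (3).

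The authors' processing notes name STAR for alignment, featureCounts for counting and the genome build danRer10. Their versions, the annotation release and the strand setting are not given in the sources used here. One deposited table holds raw read counts per Ensembl gene, and the other deposited table holds TPM (transcript abundance scaled for gene length and library by the authors). Each has 35572 lines, of which 455 repeat an identifier, leaving 35117 unique identifiers. Symbols came from the deposited tables and a gene name table, and 27289 identifiers had one.

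Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, its filter on low counts by group (15247 genes kept) and a quasi-likelihood fit of all 17 libraries in which each group has its own mean. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called. The common biological coefficient of variation was 2.02, with 12 residual and 10.7 prior degrees of freedom. CPM are counts scaled to the TMM-adjusted library size, given as mean and SD. Where a group had 0 counts in every library, a fold is a lower bound against 3 counts over the group (0.0593 CPM for MLCs, 0.0548 for cLCs, 0.0808 for keratinocytes, 0.0473 for neutrophils, 0.0496 for T cells). Amplified reads without molecular identifiers are not independent molecules, so such floors cover counting error only.

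The comparisons were MLCs with cLCs, keratinocytes, neutrophils and T cells, and cLCs with keratinocytes. Also counted were genes called above all 4 other groups and genes called in 2 groups over a shared reference. Gene lists, the rule for named genes, the tests and their alternatives were fixed before the data were examined. The rule names, for MLCs against cLCs and against keratinocytes, the 10 called genes per direction with the largest fold, a mean of at least 50 CPM in the higher group, no overlap between the groups' libraries and a symbol that is not a placeholder. For the other comparisons it names 5, for genes above all others 10 in MLCs and cLCs and 5 in the other groups, and for shared genes 10. Members of lists are the examples with the smallest adjusted p, and the reporter genes.

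The 26 lists were reporter genes, myeloid core, MHC class II presentation, MHC class I processing, Langerhans and dendritic cells, phagocytosis and complement, innate sensing, cytokines and chemokines, endocytosis and lysosome, keratins, epithelial junctions, ectodermal transcription factors, myeloid transcription factors, ionocytes, mucous and club cells, T cells, neutrophils, melanophores, fibroblasts and osteoblasts, endothelial cells, erythrocytes, B and NK cells, neuroepithelial cells and neuromasts, cell cycle, immediate early and stress genes, and oxidative phosphorylation. Of 599 distinct symbols 577 matched. Genes can stand in several lists. The 23 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01), repeated with an estimated correlation, and with fry. Their adjusted p values are over the 23 lists of a comparison. Camera compares a list with the other genes, and fry does not.

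Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, at least 10 CPM in 3 libraries, limma with a trend on log2(TPM + 1) for genes of at least 1 TPM in 3 libraries, only the libraries of the 2 groups compared, a test for a fold above 2, the replicate number as a block, and leaving out each library. For the profile comparison they were Pearson correlation, log2(TPM + 1), log2(TPM + 0.1) and no filter. The median log2 fold change of all genes with TMM and with RLE scaling was 0.13 and 0.21 for MLCs against cLCs, 0.30 and 0.08 for MLCs against keratinocytes, 0.26 and 0 for cLCs against keratinocytes, and 1.08 and 1.00 for MLCs against neutrophils. Leaving out the 4 libraries with under 6000 genes was added after seeing the data.

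The fits were tested on simulated data, with counts drawn for MLCs against cLCs in which 50 genes per fold size were changed. At 16-fold, 64-fold and 256-fold edgeR recovered 4%, 26% and 66% of the changed genes, with 2 unchanged genes among 51 called. DESeq2 recovered 32%, 70% and 80%, with 289 unchanged genes among 381 called. For this reason its larger counts stand beside those of edgeR and not in their place. Limma on log2(CPM + 1) recovered 4%, 24% and 42%, with 2 unchanged genes among 38 called, and limma on TPM was not simulated. The counts were drawn with the dispersions of the edgeR fit, so the simulation is not an even test of the tools. Other splits of the libraries were counted for each comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading and plotting. Coordinates, raw reads and imaging were not analysed here.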

Results

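Transcripts were sequenced from hand-picked cells of adult zebrafish epidermis in 17 libraries of 5 groups. The groups were 4 libraries of MLCs, 4 of cLCs, 3 of keratinocytes, 3 of neutrophils and 3 of T cells. MLCs and cLCs were both picked from a transgenic line in which the promoter of mpeg1, a gene of macrophages, drives a reporter that switches color after recombination. Keratinocytes carried a krt4 reporter, T cells an lck reporter and neutrophils an lyz reporter. The abbreviations MLC and cLC are not spelled out in the sources used here. Total gene counts were 5837662, 21343723, 17064773 and 15765265 in MLCs replicates 1 to 4, and 6158350, 19046921, 15748369 and 14248945 in cLCs replicates 1 to 4. They were 22118546, 10557601 and 12073743 in keratinocytes, 24596883, 14082748 and 14786001 in neutrophils, and 16041037, 12128321 and 16499725 in T cells. Genes with at least 1 count numbered 4484 to 16921 per library. The libraries cLCs replicate 3 (5662), cLCs replicate 4 (4484), neutrophils replicate 2 (5071) and neutrophils replicate 3 (4556) had fewer than 6000, and the other 13 had 8564 or more. Levels are CPM, counts scaled to library size, with the SD between libraries, with n = 4 for MLCs and cLCs and n = 3 for the other groups. Chromosome positions are not given in the sources used here, so genes are identified by symbol and, where symbols repeat, by identifier.

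**Figure D1:**
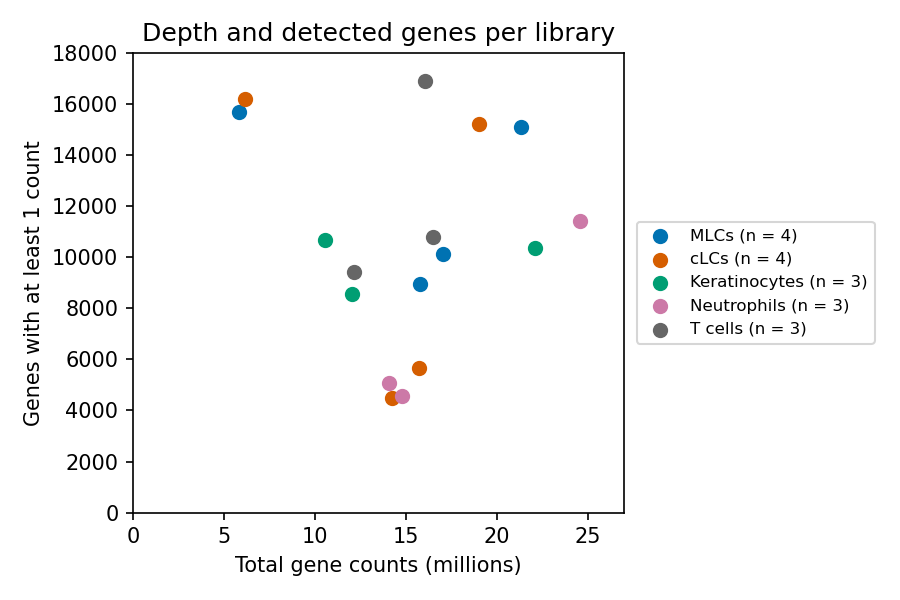
Total gene counts (x axis) and genes with at least 1 count (y axis) of each library, 1 point per library, colored by group. The 4 libraries with 4484 to 5662 genes lie at 14082748 to 15748369 counts, within the range of the other 13.

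Each reporter gene was read in the group picked for it. The macrophage gene mpeg1.1 stood at 1276 ± 321 CPM in MLCs and 5012 ± 3298 CPM in cLCs, and at 0.12 ± 0.207 CPM in keratinocytes. The keratin gene krt4 stood at 26070 ± 20280 CPM in keratinocytes, 265 ± 256.2 CPM in MLCs and 8.08 ± 11.6 CPM in cLCs. The lysozyme gene lyz reached 1823 ± 620 CPM in neutrophils and 0.115 ± 0.230 CPM in MLCs, and the T cell kinase gene lck reached 622 ± 57.7 CPM in T cells and 3.31 ± 6.06 CPM in MLCs. As a list, the 4 reporter genes were not called between MLCs and cLCs (camera adjusted p = 0.938), where their mean and median log2 fold changes were 1.36 and 1.18 and the test's direction was down.

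The next question was which group the whole MLC profile resembles. Over 15247 genes, the Spearman correlation of each MLC library with the mean profile was 0.560 ± 0.041 for cLCs and 0.446 ± 0.033 for keratinocytes (SD, n = 4). It was 0.496 ± 0.032 for neutrophils, 0.473 ± 0.041 for T cells, and 0.783 ± 0.040 for MLCs themselves, where each library was left out of the mean. Each of the 4 MLC libraries was nearer to cLCs than to keratinocytes, by 0.115 ± 0.017. The exact two-sided sign-flip test over the 4 libraries gave p = 0.13, the smallest it can give. The correlation is across genes, which are not independent replicates. Without cLCs replicate 2 the difference was 0.085, and without a low-count filter it was 0.064. Libraries of cLCs (0.331 ± 0.056), neutrophils (0.304 ± 0.038) and T cells (0.333 ± 0.006) correlated less with the keratinocyte mean than MLC libraries did. Of the other groups' means, that of MLCs was nearest to keratinocyte libraries (0.438 ± 0.035, against 0.349 ± 0.021 for cLCs). T cell libraries correlated with the cLC mean at 0.52 ± 0.047, so nearness to cLCs is not particular to MLCs. The first principal component held 20.5% of the variance and fell with the number of detected genes (Spearman correlation -0.858 over the 17 libraries), and the second held 16.7%.

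**Figure D2:**
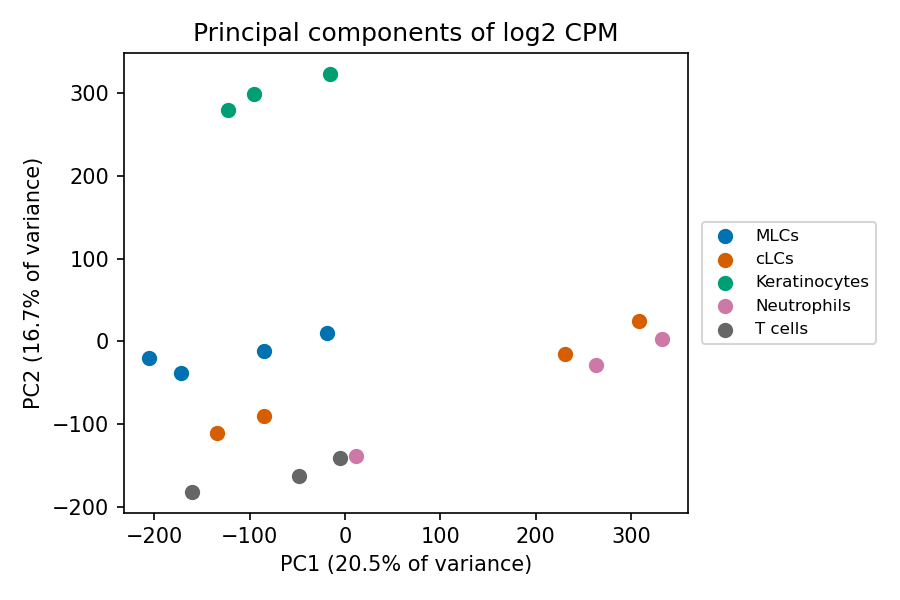
First (x axis) and second (y axis) principal components of log2 CPM over 15247 genes, 1 point per library, colored by group. The first component holds 20.5% and the second 16.7% of the variance.

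MLCs and cLCs, the populations of one reporter line, were compared to find what separates them. cdh1, which encodes E-cadherin, the cell adhesion protein of epithelia, was higher in MLCs at 1086 ± 376 CPM against 8.98 ± 11.7 CPM (edgeR adjusted p = 0.0482), in 4 of 4 MLC libraries above every cLC library. ptprc, the leukocyte common antigen CD45, was lower in MLCs, at 0.0998 ± 0.200 CPM against 490 ± 262 CPM in cLCs (adjusted p = 0.00311). The complement genes c1qc (0.0499 ± 0.0998 against 2084 ± 2599 CPM), c1qa (0.0499 ± 0.0998 against 659 ± 477 CPM) and the related c1ql1 (0.30 ± 0.599 against 4970 ± 7550 CPM) were also lower. So were cd4-1 and cd8a, coreceptor genes known from T cells, at 0.0499 ± 0.0998 against 582 ± 341 CPM and 0.0499 ± 0.0998 against 510 ± 574 CPM. The connexin gene cx32.2 was at least 10710-fold lower (635 ± 651 CPM in cLCs) and nrros at least 1551-fold lower (92.0 ± 27.1 CPM in cLCs), with 0 counts in every MLC library. Also lower were mfap4, a macrophage gene in zebrafish (0.200 ± 0.399 against 2201 ± 3207 CPM), a paralog named MFAP4 (identifier ENSDARG00000088745, 0 against 318.6 ± 388.6 CPM) and asgr1c.1 (0.0499 ± 0.0998 against 436 ± 416 CPM). Reads of these paralogs cannot be separated further here.

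In all, 2 genes were higher and 24 lower in MLCs than in cLCs at an edgeR adjusted p under 0.05. The second higher gene, zgc:193505, was chosen after its values were seen, since its name is a placeholder. It stood at 47.0 ± 78.5 CPM in MLCs and 3990 ± 3713 CPM in keratinocytes, with 0 counts in cLCs. All 26 calls were also made by DESeq2 and by limma on TPM. With the replicate number as a block or with no filter on low counts, the count lower was several times larger (given below). The count higher was more than an order of magnitude larger in both, so the count of 2 depends on these settings. DESeq2 called 553 higher and 434 lower and limma 800 and 424, which made the share called higher 7.69% with edgeR, 56.0% with DESeq2 and 65.4% with limma. Without the 4 libraries with under 6000 genes, an alternative chosen after seeing the data, 21 genes were higher and 136 lower. The counts higher and lower became 0 and 4 without cLCs replicate 1, 4 and 37 without keratinocytes replicate 1, 0 and 8 without MLCs replicate 1, 0 and 1 without MLCs replicate 2, 1 and 2 without MLCs replicate 3, 0 and 0 without MLCs replicate 4 and 6 and 42 without neutrophils replicate 3. The count of higher genes became 25 without cLCs replicate 2, 0 without cLCs replicate 3, 0 without cLCs replicate 4, 4 without neutrophils replicate 1, 4 without neutrophils replicate 2, 5 without T cells replicate 1, 5 without T cells replicate 2 and 6 without T cells replicate 3.

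The list of epithelial junction genes was called higher in MLCs than in cLCs (camera adjusted p = 9.03e-15; adjusted p = 0.182 with an estimated correlation). Of 45 tested members, 1 (cdh1) passed over all genes and 24 adjusted over the list alone, and all 45 had a fitted log2 fold change above 0. Examples are pkp3a, a desmosome gene (171 ± 122 against 1.04 ± 1.25 CPM), oclnb, an occludin gene (146 ± 33.9 against 1.49 ± 1.87 CPM), and spint2, a protease inhibitor gene (1058 ± 399 against 8.95 ± 11.8 CPM). Keratin genes had 0 of 13 members past the test over all genes, and 4 higher and 1 lower adjusted over the list alone; krt5 stood at 575 ± 726 CPM in MLCs and 9.61 ± 15.1 CPM in cLCs (adjusted p = 0.282). Ectodermal transcription factors had 0 of 20 members past the test over all genes by edgeR (7 by DESeq2 and 6 by limma on TPM) and 1 adjusted over the list alone, with elf3 at 172 ± 112 against 1.27 ± 2.55 CPM (camera adjusted p = 0.0147; adjusted p = 0.454 with an estimated correlation).

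The list of myeloid core genes was called lower in MLCs than in cLCs (camera adjusted p = 4.83e-11; adjusted p = 0.0987 with an estimated correlation). Of 26 members, 4 passed over all genes (ptprc, grap2a, cebpa and mfap4) and 13 adjusted over the list alone, and the log2 fold change was below 0 for 16 and above 0 for 10. The adaptor gene grap2a stood at 0.0499 ± 0.0998 against 132 ± 75.7 CPM and cebpa, a myeloid transcription factor gene, at 0.216 ± 0.390 against 224 ± 129 CPM. Phagocytosis and complement genes had 2 of 22 members lower (c1qa and c1qc), 10 lower and 1 higher adjusted over the list alone (adjusted p = 3.81e-09; adjusted p = 0.182 with an estimated correlation). Myeloid transcription factors had 1 of 30 members lower (cebpa) and 5 adjusted over the list alone (adjusted p = 0.000244; adjusted p = 0.347 with an estimated correlation). In the T cell list 2 of 31 members were lower (cd4-1 and cd8a), and camera gave adjusted p = 0.15. Langerhans and dendritic cell genes went both ways, with cdh1 higher and, adjusted over the list alone, 4 higher and 3 lower of 19 (adjusted p = 0.938). Among those that pass over the list alone, csf1ra, the receptor gene for colony-stimulating factor 1, had 0 counts in MLCs and 110 ± 57.9 CPM in cLCs, and epcam, an epithelial adhesion gene, 2565 ± 1552 against 22.8 ± 43.7 CPM.

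Camera also called 6 other lists lower in MLCs. The first was endocytosis and lysosome genes (camera adjusted p = 3.26e-07, and adjusted p = 0.347 with an estimated correlation), with protease genes among its members. Of these, ctsd stood at 82.6 ± 43.9 against 2830 ± 2461 CPM and ctsba at 124 ± 44.1 against 2331 ± 1265 CPM. The others were cytokine and chemokine genes (0.000821, and 0.347), immediate early and stress genes (0.00049, and 0.347), MHC class II presentation (0.0368, and 0.44), cell cycle (0.0446, and 0.615) and endothelial genes (0.0446, and 0.347). In the immediate early, MHC class II, cell cycle and endothelial lists (the last with 3 tested members) no member passed, also adjusted over the list alone. No call was made for oxidative phosphorylation (0.105), innate sensing (0.0897), ionocyte (0.0897), mucous and club cell (0.0897), neutrophil (0.053), fibroblast and osteoblast (0.241), B and NK cell (0.241), MHC class I (0.683) or keratin genes (0.938). Of the erythrocyte genes 2 were tested, too few for a list test, and of the melanophore and the neuroepithelial and neuromast genes 0 passed the count filter. The 18 lists with 0 called members by edgeR held 82 list entries at an unadjusted p under 0.05, 47 called by DESeq2 and 46 by limma on TPM. The self-contained test fry called 6 of the 23 lists. Lower by fry were myeloid core (fry adjusted p = 5.62e-05), phagocytosis and complement (0.0049) and myeloid transcription factor genes (0.0351). Higher were epithelial junction (0.000216), ectodermal transcription factor (0.00501) and mucous and club cell genes (0.0351), the last without a call by camera. The 6 other lists called lower by camera were not called by fry (fry adjusted p of 0.274 to 0.76).

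**Figure D3:**
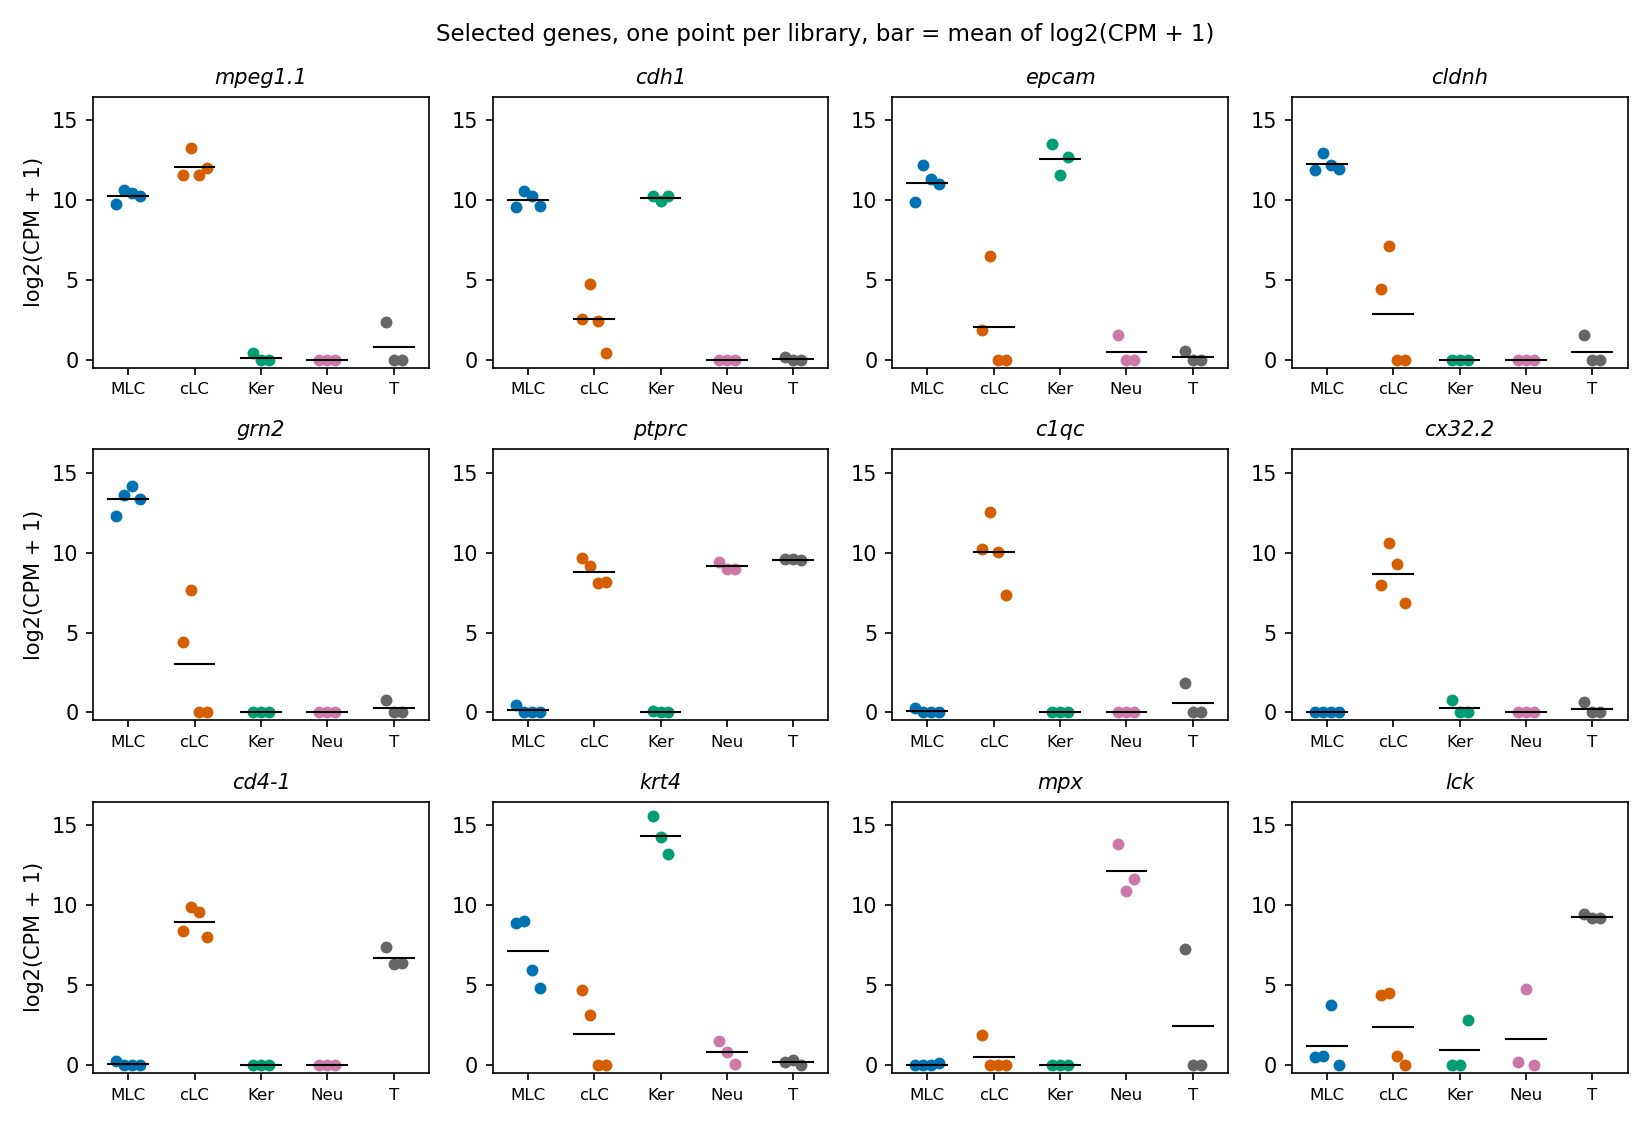
Level of 12 genes as log2(CPM + 1) on the y axis, 1 point per library and the mean as a bar, for MLCs, cLCs, keratinocytes (Ker), neutrophils (Neu) and T cells (T) on the x axis. cdh1 stands at 1086 ± 376 CPM in MLCs and 8.98 ± 11.7 CPM in cLCs, and ptprc at 0.0998 ± 0.200 and 490 ± 262 CPM.

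**Figure D4:**
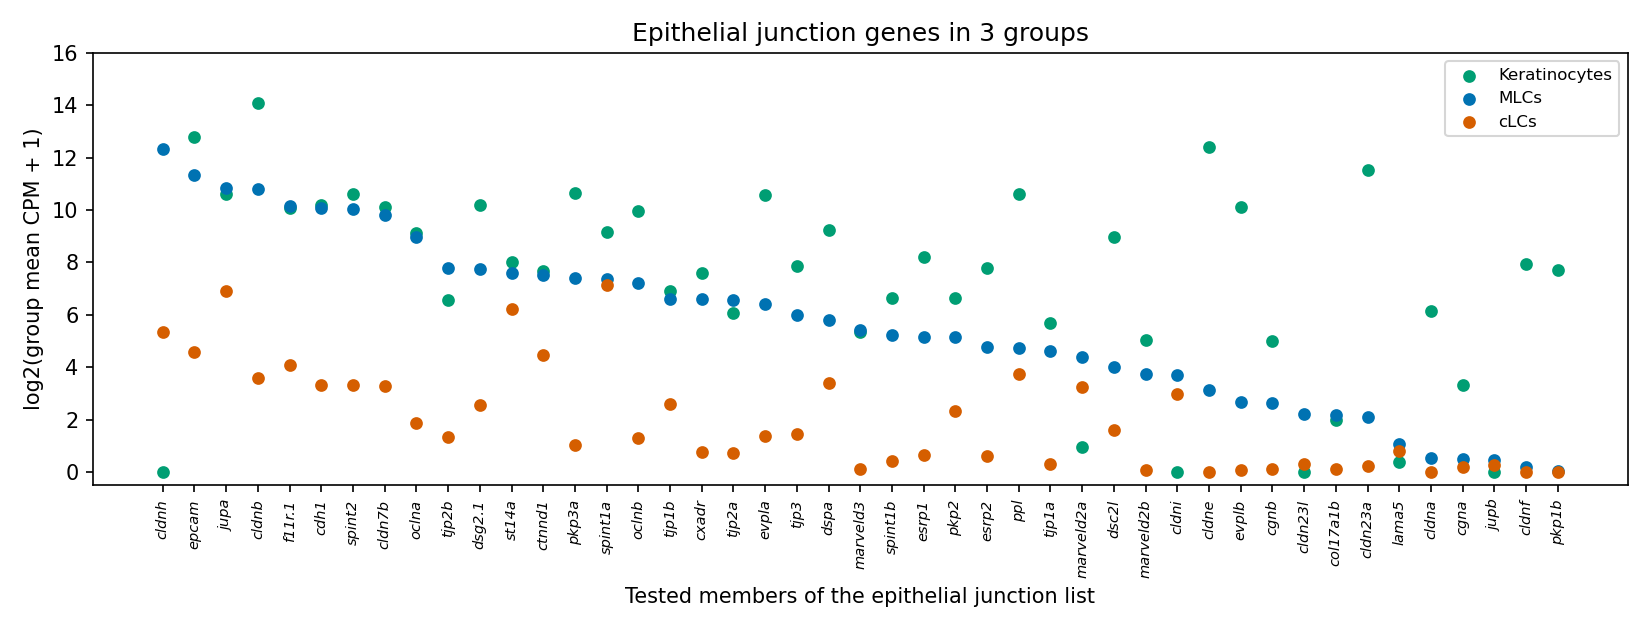
Group mean levels, as log2(CPM + 1) on the y axis, of the 45 tested epithelial junction genes on the x axis, in keratinocytes, MLCs and cLCs, ordered by the MLC mean. All 45 have a fitted log2 fold change above 0 between MLCs and cLCs.

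MLCs were compared with keratinocytes, the epithelial cells around them. rac2, a GTPase gene of blood cells, was higher in MLCs, at 1603 ± 630 CPM against 0.0171 ± 0.0296 CPM (edgeR adjusted p = 9.37e-06), and spi1a, which encodes a PU.1 transcription factor, at 1182 ± 423 against 0.137 ± 0.237 CPM. Genes with 0 counts in every keratinocyte library included grn2, a granulin gene (11690 ± 5497 CPM, at least 144800-fold), the claudin gene cldnh (5094 ± 1860 CPM, at least 63070-fold), il22ra2, which encodes a soluble receptor of interleukin 22 (3052 ± 1898 CPM), the chitinase gene chia.6 (2638 ± 991 CPM) and the chemokine receptor gene xcr1a.1 (934 ± 933 CPM). ptprja (834 ± 118 CPM), crfb15 (771 ± 418 CPM), the adaptor gene fybb (671 ± 248 CPM), the transcription factor gene spic (607 ± 328 CPM) and the actin regulator gene gsna (590 ± 222 CPM) complete the 10 largest changes named. Keratinocytes were higher for krt17, a keratin gene (776 ± 568 CPM, at least 13080-fold), the mucin gene muc13a (279 ± 223 CPM), the oxidase gene nox1 (268 ± 177 CPM) and tgm1, a transglutaminase gene of the cornified envelope (172 ± 108 CPM), each with 0 counts in MLCs. The same held for eps8l1a, plekhs1, plcd1a, arid6, gfpt2 and ponzr10, at 159 to 244 CPM in keratinocytes.

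By list, 12 of 26 myeloid core genes were higher and 1, cebpa, was lower in MLCs (0.216 ± 0.390 against 675 ± 584 CPM), with 16 and 2 adjusted over the list alone (camera adjusted p = 7.12e-10; adjusted p = 0.129 with an estimated correlation). Cytokine and chemokine genes had 5 of 35 higher, among them the chemokine receptor genes ccr9a (3112 ± 709 against 0.0684 ± 0.118 CPM) and cxcr4b (2024 ± 684 against 0.188 ± 0.326 CPM), with 7 adjusted over the list alone (adjusted p = 0.00658; adjusted p = 0.529 with an estimated correlation). Phagocytosis genes had 4 of 22 higher and 8 adjusted over the list alone, with the oxidase subunit gene ncf1 at 1571 ± 614 against 0.0342 ± 0.0592 CPM (adjusted p = 0.000855; adjusted p = 0.529 with an estimated correlation). MHC class II genes had 1 of 14 higher, cd83 at 1525 ± 723 against 0.137 ± 0.237 CPM, and 3 adjusted over the list alone (adjusted p = 0.0167; adjusted p = 0.529 with an estimated correlation). Keratins had 1 of 13 lower, krt17, and 1 higher, krt18b (1602 ± 503 against 0.0684 ± 0.118 CPM), with 6 and 1 adjusted over the list alone (adjusted p = 4.19e-05 downward; adjusted p = 0.249 with an estimated correlation). Epithelial junction genes had 3 of 45 lower, pkp1b, cldn23a and cldnf, and 1 higher, cldnh, with 5 and 1 adjusted over the list alone (adjusted p = 4.19e-05 downward; adjusted p = 0.529 with an estimated correlation). Ectodermal transcription factors had 1 of 20 lower, ovol1a at 0.0499 ± 0.0998 against 142 ± 81.5 CPM, and 1 adjusted over the list alone (adjusted p = 3.03e-07; adjusted p = 0.217 with an estimated correlation). Immediate early genes had 3 of 25 lower, junba (258 ± 82.8 against 2278 ± 278 CPM), fosab (411 ± 270 against 4980 ± 1116 CPM) and jun (166 ± 84.1 against 4407 ± 1744 CPM), and 9 adjusted over the list alone (adjusted p = 1.72e-06; adjusted p = 0.249 with an estimated correlation).

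In total 219 genes were higher and 72 lower in MLCs than in keratinocytes by edgeR, 75.3% of the calls being higher. The share was 76.4% with DESeq2 (1531 and 474) and 47.0% with limma on TPM (864 and 974). In an alternative chosen after seeing the data, without the 4 libraries with under 6000 genes, 694 were higher and 376 lower. The counts higher and lower became 99 and 36 without keratinocytes replicate 1, 92 and 18 without keratinocytes replicate 2, 90 and 26 without keratinocytes replicate 3 and 142 and 15 without MLCs replicate 2. The count of lower genes became 113 without cLCs replicate 4, 20 without MLCs replicate 3, 18 without MLCs replicate 4 and 109 without neutrophils replicate 3.

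cLCs were compared with keratinocytes in the same way. Genes higher in cLCs, each with 0 counts in keratinocytes, were c1ql1 (4970 ± 7550 CPM, at least 61540-fold), the scavenger receptor gene marco (2634 ± 3121 CPM, at least 32620-fold), the complement genes c1qb (2610 ± 2849 CPM) and c1qc (2084 ± 2599 CPM), and the chemokine gene cxcl19 (1051 ± 942 CPM). Keratinocytes were higher for sult2st3, a sulfotransferase gene (9944 ± 16120 CPM), the claudin gene cldne (5430 ± 1694 CPM), the keratin gene krt1-19d (3822 ± 5239 CPM), soul2 (2396 ± 907 CPM) and lmo7a (1027 ± 432 CPM), each with 0 counts in cLCs. The mean of sult2st3 is carried by keratinocytes replicate 2, at 28550 CPM against 9.80 and 1276 CPM. For krt1-19d replicate 1 held 9856 CPM. Of 26 myeloid core genes 19 were higher in cLCs and 21 adjusted over the list alone. Among them laptm5, a lysosomal membrane gene of leukocytes, stood at 648 ± 304 against 0.0684 ± 0.118 CPM. Camera gave adjusted p = 8.38e-31, and adjusted p = 0.00145 with an estimated correlation. Phagocytosis genes had 9 of 22 higher and 18 adjusted over the list alone (camera adjusted p = 2.93e-15), a call that held with an estimated correlation (adjusted p = 0.0344). Epithelial junction genes had 13 of 45 lower and 31 adjusted over the list alone, with 1 higher, and pkp3a stood at 1.04 ± 1.25 against 1619 ± 1339 CPM (camera adjusted p = 1.44e-20; adjusted p = 0.0592 with an estimated correlation). Ectodermal transcription factors had 3 of 20 lower and 10 adjusted over the list alone (adjusted p = 4.91e-12), a call that held with an estimated correlation (adjusted p = 0.0344). Keratins had 6 of 13 lower and 1 higher, with 10 and 2 adjusted over the list alone (adjusted p = 0.000359; adjusted p = 0.211 with an estimated correlation).

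Between cLCs and keratinocytes 308 genes were higher and 206 lower by edgeR, a share of 59.9% higher against 51.7% with RLE scaling, 61.9% with DESeq2 (1645 and 1013) and 36.0% with limma on TPM (742 and 1318). Camera called 16 of 23 lists, 3 of them also with an estimated correlation. Leaving out the 4 libraries with under 6000 genes, chosen after seeing the data, gave other counts: 824 were higher and 193 lower. The counts higher and lower became 203 and 99 without cLCs replicate 1, 189 and 131 without cLCs replicate 2, 129 and 97 without keratinocytes replicate 1, 115 and 83 without keratinocytes replicate 2 and 124 and 108 without keratinocytes replicate 3. The count of lower genes became 111 without cLCs replicate 3.

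Neutrophils, cells of the myeloid lineage, were compared with MLCs next. Genes higher in MLCs, each with 0 counts in neutrophils, were grn2 (11690 ± 5497 CPM, at least 247300-fold), cldnh (5094 ± 1860 CPM), il22ra2 (3052 ± 1898 CPM), the chemokine gene ccl35.1 (1369 ± 414 CPM) and il12bb, a subunit gene of interleukin 12 (1338 ± 747 CPM). Neutrophils were higher for il6r, a receptor gene of interleukin 6 (2272 ± 1513 CPM, at least 38280-fold), ppdpfa (1160 ± 732 CPM), the protease genes adam8a (1149 ± 660 CPM) and cpa5 (985 ± 1088 CPM), each with 0 counts in MLCs, and for mpx, the myeloperoxidase gene (0.0191 ± 0.0382 against 6647 ± 7153 CPM). The neutrophil list had 9 of 28 members lower in MLCs and, adjusted over the list alone, 21 lower and 1 higher (camera adjusted p = 9.03e-35), a call that held with an estimated correlation (adjusted p = 0.0105). Epithelial junction genes had 16 of 45 higher in MLCs and 34 adjusted over the list alone, with cdh1 at 1086 ± 376 CPM against 0 counts (adjusted p = 2.29e-16; adjusted p = 0.148 with an estimated correlation). MHC class II genes had 4 of 14 higher and 5 adjusted over the list alone, such as cd74a, the invariant chain gene (18300 ± 8468 against 9.84 ± 17.1 CPM; adjusted p = 1.21e-05; adjusted p = 0.148 with an estimated correlation). Myeloid core genes went both ways, 2 higher and 4 lower of 26, with ptprc at 0.0998 ± 0.200 against 570 ± 92.7 CPM and slc7a7 at 93.9 ± 47.7 CPM against 0 counts (4 and 5 adjusted over the list alone; camera adjusted p = 6.6e-05 downward; adjusted p = 0.256 with an estimated correlation). In 2 called lists the signs differed: phagocytosis genes had a camera direction of down (adjusted p = 0.036; adjusted p = 0.695 with an estimated correlation) but a mean and median log2 fold change of 0.86 and 0.75, and myeloid transcription factors (adjusted p = 0.0187; adjusted p = 0.638 with an estimated correlation) had a mean of -0.37 and a median of 0.

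In total 234 genes were higher and 56 lower in MLCs than in neutrophils by edgeR, against 2310 and 383 by DESeq2 and 952 and 346 by limma on TPM. Without the 4 libraries with under 6000 genes, 2 of which are neutrophil libraries and which were left out after seeing the data, 96 were higher and 92 lower. That fit has 1 neutrophil library, which is assumed to vary like the other groups. The counts higher and lower became 405 and 92 without cLCs replicate 4, 119 and 30 without MLCs replicate 1, 111 and 18 without MLCs replicate 2, 130 and 22 without MLCs replicate 3, 136 and 24 without MLCs replicate 4 and 37 and 27 without neutrophils replicate 2. The count of higher genes became 62 without neutrophils replicate 3; the count of lower genes became 86 without keratinocytes replicate 1 and 37 without neutrophils replicate 1.

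The comparison with T cells set MLCs against lymphocytes of the same tissue. Higher in MLCs, with 0 counts in T cells, were spint2 (1058 ± 399 CPM, at least 21310-fold), nipal4 (786 ± 150 CPM), the annexin gene anxa5b (561 ± 139 CPM) and s100u (406 ± 112 CPM), and grn2 stood at 11690 ± 5497 against 0.238 ± 0.412 CPM. T cells were higher for the chemokine genes ccl38a.4 (1689 ± 1206 CPM, at least 28460-fold) and ccl38a.5 (858 ± 726 CPM), the receptor gene tnfrsf9b (1296 ± 66.2 CPM), nab1a (909 ± 75.1 CPM) and plp2a (517 ± 44.9 CPM), each with 0 counts in MLCs. The T cell list had 9 of 31 members lower in MLCs and 17 adjusted over the list alone. Examples are zap70, a kinase gene of T cell receptor signalling (434 ± 67.5 CPM against 0 counts), and sla2 (0.0499 ± 0.0998 against 1009 ± 164 CPM). Camera gave adjusted p = 3.25e-22, and adjusted p = 0.00265 with an estimated correlation. Epithelial junction genes had 11 of 45 higher and 32 adjusted over the list alone, with oclnb at 146 ± 33.9 CPM against 0 counts (adjusted p = 1.82e-19; adjusted p = 0.139 with an estimated correlation). Ectodermal transcription factors had 2 of 20 higher and 5 adjusted over the list alone (adjusted p = 0.000231; adjusted p = 0.496 with an estimated correlation). Mucous and club cell genes had 1 of 6 higher, icn at 5857 ± 2402 against 220 ± 99.2 CPM (adjusted p = 0.0337; adjusted p = 0.548 with an estimated correlation). The ccl38 genes are paralogs whose reads cannot be separated further here.

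In total 118 genes were higher and 66 lower in MLCs than in T cells by edgeR, 64.1% being higher. The share was 73.8% with DESeq2 (982 and 349) and 41.6% with limma on TPM (838 and 1176). Without the 4 libraries with under 6000 genes, an alternative chosen after seeing the data, 552 were higher and 232 lower. The counts higher and lower became 47 and 33 without MLCs replicate 1, 35 and 18 without MLCs replicate 2, 49 and 20 without MLCs replicate 3, 47 and 17 without MLCs replicate 4, 59 and 23 without T cells replicate 1, 0 and 2 without T cells replicate 2 and 3 and 17 without T cells replicate 3. The count of higher genes became 214 without cLCs replicate 4.

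Genes above each of the 4 other groups mark the identity of a group. Keratinocytes had 47, led by krt17, muc13a, arid6, anxa1d, an annexin gene (142.9 ± 10.4 CPM), and ccl20b, a chemokine gene (141.6 ± 56.9 CPM), with 0 counts in the other 14 libraries for these 5. T cells had 4, with ccl38a.5, ccl38.6 (815 ± 504 CPM), sla2 and si:ch211-112c15.8, the last chosen after its values were seen. cLCs had 2, shtn2 (224 ± 96.6 CPM against 0.0499 ± 0.0998 CPM in MLCs) and ms4a17a.10 (2392 ± 2491 CPM against 0.749 ± 0.996 CPM in MLCs). MLCs had 0 by edgeR, with 140 genes at 4 unadjusted p values under 0.05, 42 by DESeq2 and 283 by limma on TPM. A count of 0 does not show that MLCs lack such genes, as edgeR recovered 26% of simulated 64-fold changes. For example, grn2 stood at 11690 ± 5497 CPM in MLCs and 54.91 ± 96.95 CPM in cLCs. The levels of cldnh were 5094 ± 1860 and 40.02 ± 66.91 CPM, and neither gene was called between these groups. Neutrophils had 0 by edgeR, with 54 at unadjusted p, 8 by DESeq2 and 117 by limma on TPM. In an alternative chosen after seeing the data, without the 4 libraries with under 6000 genes, the counts were 2 for MLCs, 1 for cLCs, 36 for keratinocytes, 0 for neutrophils and 0 for T cells. Each of these rests in part on the 1 neutrophil library left, assumed to vary like the other groups. For MLCs it was 3 without cLCs replicate 2. For cLCs it was 0 without cLCs replicate 1, 0 without cLCs replicate 2, 1 without cLCs replicate 3, 6 without cLCs replicate 4, 4 without keratinocytes replicate 1, 1 without keratinocytes replicate 3, 1 without MLCs replicate 1, 0 without MLCs replicate 2, 1 without MLCs replicate 3, 0 without MLCs replicate 4, 4 without neutrophils replicate 1, 5 without neutrophils replicate 3, 6 without T cells replicate 1, 0 without T cells replicate 2 and 0 without T cells replicate 3. For keratinocytes it was 27 without cLCs replicate 1, 27 without cLCs replicate 2, 22 without keratinocytes replicate 1, 10 without keratinocytes replicate 2, 16 without keratinocytes replicate 3, 11 without MLCs replicate 2, 15 without MLCs replicate 3, 13 without MLCs replicate 4, 17 without T cells replicate 1, 20 without T cells replicate 2 and 20 without T cells replicate 3. For neutrophils it was 1 without neutrophils replicate 3 and 5 without T cells replicate 1. For T cells it was 0 without cLCs replicate 1, 0 without cLCs replicate 2, 8 without cLCs replicate 4, 1 without MLCs replicate 1, 1 without MLCs replicate 2, 0 without neutrophils replicate 2, 0 without neutrophils replicate 3, 0 without T cells replicate 2 and 0 without T cells replicate 3.

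The shared counts show which part of each difference 2 groups have in common. MLCs and cLCs were both above keratinocytes for 174 genes, led by gsna (405.7 ± 222.7 CPM in cLCs), fybb, the phosphatase gene acp5a (289.3 ± 101.0 CPM in MLCs), the nuclear receptor gene nr4a2b (328.5 ± 76.6 CPM in MLCs) and elovl5, a fatty acid elongase gene (408.8 ± 151.5 CPM in MLCs). wipf1b, the interferon gamma receptor gene ifngr2, the talin gene tln1, klhl6 and ccr9a complete the 10. Independent lists of 219 and 308 genes would share 4.42, which does not allow for the shared keratinocyte libraries, too few to split. Simulated unchanged groups compared with a common reference shared 0.15 on average. Their lists held 0.25 and 0.35 genes on average, so this overlap could not come near 174. The correlation of the log2 fold changes was 0.749, against 0.59 in the simulation, and the covariance 19.3 against 5.77. MLCs and keratinocytes were both above cLCs for 2 genes, cdh1 (1159 ± 137 CPM in keratinocytes) and zgc:193505. Independent lists of 2 and 206 genes would share 0.027. Simulated groups shared 0.05, from lists of 0.15 and 0.25 genes on average. For zgc:193505 the MLC level was 47.0 ± 78.5 CPM against 3990 ± 3713 CPM in keratinocytes, and most of it came from MLCs replicate 1 (165 CPM), the MLC library with the most keratin, so shared expression is not claimed for this gene. With the cLC libraries split so that each comparison had its own 2, the overlap was 2.33 on average, from 0 to 14 over 6 splits, and the correlation was 0.223. Without that split it was 0.491, against 0.452 in the simulation of unchanged groups that share the cLC libraries. Without the 4 libraries with under 6000 genes the counts were 503 over keratinocytes and 15 over cLCs. The count of MLCs and cLCs over keratinocytes was 81 without keratinocytes replicate 1, 77 without keratinocytes replicate 2 and 80 without keratinocytes replicate 3. The count of MLCs and keratinocytes over cLCs was 0 without cLCs replicate 1, 20 without cLCs replicate 2, 0 without cLCs replicate 3, 0 without cLCs replicate 4, 4 without keratinocytes replicate 1, 0 without MLCs replicate 1, 0 without MLCs replicate 2, 1 without MLCs replicate 3, 0 without MLCs replicate 4, 4 without neutrophils replicate 1, 4 without neutrophils replicate 2, 6 without neutrophils replicate 3, 5 without T cells replicate 1, 5 without T cells replicate 2 and 6 without T cells replicate 3.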

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

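All tests of explanations in this part were chosen after the result was seen, and the values far from their group come from a fixed criterion. In MLCs and cLCs, 41 of 149 reported values had 1 library far from the other 3 of its group. By chance the criterion is met in about 1 in 20 cases for independent, normally distributed values. CPM are not such values: all 41 lay on the high side, and values of 1 library are not independent. No excess over chance is therefore claimed. In 20 of the 41, 15 of them in MLCs replicate 1, the other 3 libraries had 0 counts, so that any count meets the criterion and this rate does not apply. Of all 41, 21 were in MLCs replicate 1 and 11 in cLCs replicate 2. Groups of 3 were not tested. The outlying values in MLCs replicate 1 were 0.200 CPM for asgr1c.1, c1qa, c1qc, cd4-1, cd8a, grap2a, ovol1a, shtn2, sla2 and tmem173, 1.2 CPM for c1ql1 and 0.599 CPM for ccl34a.4 and cldnf. It also held 0.799 CPM for cebpa and mfap4, 13.2 CPM for cldn23a and 189.5 CPM for ctsba. Further values there were 231 CPM for egr1, 1661 CPM for krt5 and 0.399 CPM for ptprc. Others were 165 CPM for zgc:193505. The outlying values in MLCs replicate 2 were 0.0653 CPM for ccl38.6 and pkp1b, 30890 CPM for cd74a and 2601 CPM for cd83. It also held 2349 CPM for krt18b and 1650 CPM for spint2. The outlying values in MLCs replicate 3 were 12.4 CPM for lck. The outlying values in MLCs replicate 4 were 0.459 CPM for lyz and 0.0765 CPM for mpx. The outlying values in cLCs replicate 2 were 6877 CPM for c1qb, 16250 CPM for c1ql1 and 3775 CPM for ccl34a.4. It also held 139 CPM for cldnh, 10530 CPM for cxcr4b and 5.09 CPM for elf3. Further values there were 88.3 CPM for epcam, 199.6 CPM for grn2 and 6990 CPM for mfap4. Others were 9898 CPM for mpeg1.1 and 964 CPM for rac2.

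The epithelial junction genes of MLCs were the first pattern weighed. RNA or cells of keratinocytes in the MLC libraries would bring the abundant keratins at the same share of their keratinocyte level, but in each MLC library the median share of the junction genes was at least 6.94 times that of the 5 abundant keratins, and cldnh has no counts in keratinocytes. That source remains open for 8 members at or under the highest keratin share (4.69%, from group means), such as cldne, evplb and dsc2l. Of these, 7 were highest in MLCs replicate 1, the MLC library with the most keratin, where the highest keratin share was 15.6%. The keratinocytes compared were picked by a krt4 reporter. Epithelial cells with less keratin RNA were not tested and remain open as a source for the whole list. Zeros in the cLC libraries with few genes do not account for the list. Its median log2 ratio of group means was 5.69, and it was 4.53 without the 4 libraries. With RLE scaling the ratio was 5.96. The median shift in log2 fold change from TMM to RLE was 0.185, too small for this exchange to test scaling as a cause. For the 33 members above 4.69%, a candidate explanation is that MLCs express part of an epithelial program, a hypothesis found and tested on the same data.

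The low number of genes in cLCs replicates 3 and 4 and neutrophils replicates 2 and 3 was the second. After thinning every library to 5837662 counts these 4 still had at most 5445 genes, against at least 8359 in the other 13, so depth does not account for it. Without the 100 most abundant genes of each library they had at most 5287, against at least 8310. Loss of transcripts before sequencing, fewer picked cells and a difference between the cells were not tested and remain open.

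MLC transcripts in cLCs replicates 1 and 2 were the third. A set of 15 genes was chosen without the counts of replicate 2, as higher in MLCs than in keratinocytes, neutrophils and T cells and at 0 in cLCs replicates 3 and 4. In replicate 2 all 15 had counts, at 0.315% to 5.89% of their MLC level, and 14 lay within 4-fold of the median of 2.08%, whereas in replicate 1 12 had counts and 9 lay within 4-fold of a median of 0.456%. RNA of keratinocytes does not account for these 15, as none has counts in keratinocytes. That follows largely from their choice as higher in MLCs, so the set does not test for keratinocyte RNA in general. A common share in replicate 2 is consistent with RNA of MLCs in that library, from free RNA or a few MLCs, while for replicate 1 the counts do not decide, and expression by the cLCs themselves remains open in both.

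The counts of the report were compared with those of other splits of the same libraries. For each pair of groups the real split gave the most genes, higher and lower, 1 of 35 splits each. The other splits mix cell types within each group, which leaves little room for called genes. No conclusion on chance is therefore drawn from their low counts. The highest other counts were 0 and 0 for MLCs against cLCs (real 2 and 24), 16 and 0 for MLCs against keratinocytes (219 and 72), 5 and 109 for cLCs against keratinocytes (308 and 206), 2 and 1 for MLCs against neutrophils (234 and 56) and 2 and 1 for MLCs against T cells (118 and 66). Over 60 drawn regroupings of all libraries, the counts of genes above all others in cLCs (2), keratinocytes (47) and T cells (4) were each reached by 1 of 60 with a highest other of 0. For MLCs and neutrophils (0) all 60 gave as many. These regroupings mix cell types within each group, which leaves little room for such genes, so no conclusion on chance is drawn from their low counts. The overlap of MLCs and cLCs over keratinocytes (174) was reached by 1 of 60 (highest other 0), and that of MLCs and keratinocytes over cLCs (2) by 2 of 60, with a highest other of 12. The regrouping with 12 gave several times the real count, and the reason was not tested. That regrouping also gave 13 genes higher for MLCs against cLCs, where the real count is 2. Camera called 11 lists for MLCs against cLCs (1 of 35, highest other 10) and 9 against T cells (1 of 35, highest other 8). Other splits came close to both counts, so they do not exclude chance. Chance cannot be excluded for the number of lists camera called for MLCs against keratinocytes (8, 6 of 35 splits as many, highest other 12), cLCs against keratinocytes (16, 3 of 35, highest other 16) and MLCs against neutrophils (10, 2 of 35, highest other 10). With fry the real split gave the most lists in each comparison. For MLCs it called 6 against cLCs (highest other 2), 13 against keratinocytes (5), 10 against neutrophils (5) and 8 against T cells (2). For cLCs against keratinocytes it called 13 (highest other 12). These splits also mix cell types, so no conclusion on chance is drawn from the fry counts.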

How the results depend on the processing

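Leaving out the 4 libraries with under 6000 genes was chosen after seeing the data, and the other alternatives were fixed before the data were examined. Of 111 calls on genes the text names, 111 kept direction and side of the threshold with RLE scaling, 110 of 110 with DESeq2, 111 with limma on TPM, 109 with the replicate number as a block, 108 without the 4 libraries and 48 in every fit without 1 library, and none reversed in these fits. Of 24 results on named genes that did not pass, 4 passed with RLE scaling, 15 of 22 with DESeq2, 19 with limma on TPM, 20 with the block and 12 without the 4 libraries, a fit with 1 neutrophil library assumed to vary like the other groups. Of 54 list calls, 5 held with an estimated correlation and 40 in every fit without 1 library. With RLE scaling the result was 5 higher for MLCs against cLCs, 333 lower for cLCs against keratinocytes, 91 lower for MLCs against neutrophils, 6 for cLCs above all and 5 for MLCs and keratinocytes over cLCs. With DESeq2 there were 553 higher and 434 lower for MLCs against cLCs, 1531 higher and 474 lower for MLCs against keratinocytes, 1645 higher and 1013 lower for cLCs against keratinocytes, 2310 higher and 383 lower for MLCs against neutrophils and 982 higher and 349 lower for MLCs against T cells. The other counts of this setting were 42 for MLCs above all, 62 for cLCs above all, 183 for keratinocytes above all, 8 for neutrophils above all, 34 for T cells above all, 337 for MLCs and keratinocytes over cLCs and 1131 for MLCs and cLCs over keratinocytes. With no filter on low counts there were 141 higher and 181 lower for MLCs against cLCs, 414 higher and 222 lower for MLCs against keratinocytes, 563 higher and 384 lower for cLCs against keratinocytes, 478 higher and 196 lower for MLCs against neutrophils and 348 higher and 150 lower for MLCs against T cells. The other counts of this setting were 20 for MLCs above all, 35 for cLCs above all, 131 for keratinocytes above all, 22 for neutrophils above all, 17 for T cells above all, 87 for MLCs and keratinocytes over cLCs, 327 for MLCs and cLCs over keratinocytes and a profile difference of 0.064. With at least 10 CPM in 3 libraries the result was 5 higher for MLCs against cLCs, 5 for cLCs above all and 4 for MLCs and keratinocytes over cLCs. With the replicate number as a block there were 126 higher and 147 lower for MLCs against cLCs, 370 higher and 177 lower for MLCs against keratinocytes, 503 higher for cLCs against keratinocytes, 440 higher and 114 lower for MLCs against neutrophils and 327 higher and 117 lower for MLCs against T cells. The other counts of this setting were 27 for MLCs above all, 40 for cLCs above all, 114 for keratinocytes above all, 18 for neutrophils above all, 22 for T cells above all and 65 for MLCs and keratinocytes over cLCs. With limma on log2(TPM + 1) there were 800 higher and 424 lower for MLCs against cLCs, 864 higher and 974 lower for MLCs against keratinocytes, 742 higher and 1318 lower for cLCs against keratinocytes, 952 higher and 346 lower for MLCs against neutrophils and 838 higher and 1176 lower for MLCs against T cells. The other counts of this setting were 283 for MLCs above all, 168 for cLCs above all, 718 for keratinocytes above all, 117 for neutrophils above all, 564 for T cells above all and 233 for MLCs and keratinocytes over cLCs. With only the 2 groups compared the result was 5 higher and 47 lower for MLCs against cLCs, 694 higher and 426 lower for MLCs against keratinocytes, 503 higher and 106 lower for MLCs against neutrophils and 691 higher and 329 lower for MLCs against T cells. With a test for a fold above 2 the result was 1 higher for MLCs against cLCs. With the 4 libraries with under 6000 genes left out there were 21 higher and 136 lower for MLCs against cLCs, 694 higher and 376 lower for MLCs against keratinocytes, 824 higher for cLCs against keratinocytes, 96 higher and 92 lower for MLCs against neutrophils and 552 higher and 232 lower for MLCs against T cells. The other counts of this setting were 2 for MLCs above all, 1 for cLCs above all, 0 for T cells above all, 15 for MLCs and keratinocytes over cLCs, 503 for MLCs and cLCs over keratinocytes and a profile difference of 0.098. With an estimated correlation the result was 5 list calls. With log2(TPM + 1) the profile difference was 0.098. Leaving out 1 library at a time gave 0 to 25 for MLCs against cLCs higher, 0 to 42 for MLCs against cLCs lower, 90 to 281 for MLCs against keratinocytes higher, 15 to 113 for MLCs against keratinocytes lower and 115 to 415 for cLCs against keratinocytes higher. Such fits also gave 83 to 290 for cLCs against keratinocytes lower, 37 to 405 for MLCs against neutrophils higher, 18 to 92 for MLCs against neutrophils lower, 0 to 214 for MLCs against T cells higher and 2 to 94 for MLCs against T cells lower. They further gave 0 to 3 for MLCs above all, 0 to 6 for cLCs above all, 10 to 70 for keratinocytes above all, 0 to 5 for neutrophils above all and 0 to 8 for T cells above all. The rest gave 0 to 20 for MLCs and keratinocytes over cLCs, 77 to 218 for MLCs and cLCs over keratinocytes, 0.085 to 0.122 for the profile difference and 47 to 79 for named calls. The cause of these changes was not tested, except that fits without a library or with 2 groups hold fewer libraries. The block changed the other counts by less than 1.5 times. A gene with 0 counts in a library with few genes is limited by detection, not shown to be absent. The labels do not say that replicate numbers mark a shared day, and not every pair passed 0.1, so they were not taken to pair libraries. The residual correlation of same-numbered libraries was over 0.1 in 2 of 4 MLC and cLC pairs and in 0 pairs of other groups. Of the 4 MLC libraries, 3 correlated best with the cLC library of their own number. Total counts of MLC and cLC libraries also ran in the same order by number. Detected genes fell from replicate 1 to 4 in both, from 15684 to 8972 in MLCs and from 16200 to 4484 in cLCs. A batch shared by number therefore remains open, and the fit without a block may understate the difference between MLCs and cLCs.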

Other observations

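The test of neutrophil RNA described here was chosen after the values were seen, and it carries no explanation. T cells replicate 1 held transcripts of neutrophil genes and of genes read in cLCs. All 14 members of the neutrophil list with at least 200 CPM in neutrophils and no counts in T cells replicates 2 and 3 had counts there, at 0.341% to 2.36% (median 1.51%) of the neutrophil level. They include mpx (153 CPM against 6647 CPM in neutrophils), npsn (111 against 7361 CPM), il6r (42.1 against 2272 CPM) and lyz (21.1 against 1823 CPM). Of genes read in cLCs and with no counts in T cells replicates 2 and 3 it held c1ql1 (7.13 CPM), mpeg1.1 (4.28 CPM), marco (3.87 CPM), c1qb (3.62 CPM), mfap4 (3.06 CPM) and c1qc (2.60 CPM). Its transcripts absent from T cells replicates 2 and 3 were not of neutrophil genes alone.

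Among the immediate early genes that did not pass the edgeR test between MLCs and cLCs, fosb stood at 172 ± 53.9 against 2747 ± 2432 CPM (edgeR adjusted p = 0.261) and egr1 at 74.5 ± 105 against 1418 ± 1316 CPM (adjusted p = 0.264). The chemokine genes ccl34a.4 (0.166 ± 0.290 against 1095 ± 1798 CPM) and ccl34b.1 (0 counts against 170 ± 166 CPM) did not pass it either, at adjusted p = 0.101 and 0.158. tmem173, which encodes the nucleic acid sensor STING, stood at 0.0499 ± 0.0998 CPM in MLCs, 73.7 ± 15.4 CPM in cLCs (adjusted p = 0.0643) and 177 ± 36.4 CPM in keratinocytes (adjusted p = 0.0109). With DESeq2, limma on TPM and the block, ccl34a.4, ccl34b.1 and tmem173 did pass between MLCs and cLCs, as did fosb with limma and the block and egr1 with the block. One gene without a symbol took 3.77% to 32.7% of the counts of a library.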
